A study of Homo sapiens with 6 samples.

How the data were processed

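RNA was measured in 6 libraries of MDA-MB-231 cells, 3 with a hairpin against PML (shPML) and 3 controls (shC). The control is called a non-targeting hairpin in the design text and an empty vector in the treatment label, and the labels do not settle which. Per the labels' protocols, total RNA was extracted on columns with DNase digestion, made into libraries with the NEBNext Ultra RNA kit and sequenced in pairs on a NovaSeq instrument. Per the submitters' processing notes, reads were aligned with STAR 2.5 and counted with HTSeq 0.6.1 on hg19. The annotation release, the strand setting and the aligner options are not given in the sources used here.

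The deposited count table holds whole-number read counts for 48162 Ensembl genes, without normalization and with 1 column per library; 22876 genes were at 0 in all libraries. The deposited FPKM table holds the same genes and libraries. Its values equal the counts divided by the column total and by 1 fixed length per gene, with ratios that differ between libraries by at most 2.51e-07 of their value. Both tables held 0 columns of other samples. Current symbols were taken by Ensembl identifier, or the GENCODE 29 name where there was none, which together named 45342 genes (94.1%). GENCODE 29 is on GRCh38, not on the submitters' build, so no coordinates are given.

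Groups and replicate numbers were read from the sample titles. Library totals ranged from 17729472 to 21609927 counts, so that 3 counts, the limit that a count of 0 allows, correspond to 0.1494, 0.1467 and 0.1388 CPM in shC replicates 1, 2 and 3 and to 0.152, 0.1692 and 0.1401 CPM in shPML replicates 1, 2 and 3. Such floors and intervals cover counting error only, since reads without molecular identifiers are not independent molecules. No pair of libraries was a duplicate: a chi-square comparison of counts per gene gave 3.99 to 4.86 per gene among shPML libraries and 12.8 to 87.7 among shC libraries. Values of genes that share exonic bases with other genes in GENCODE 29 are uncertain, on either strand because the strand setting is not stated. Named genes that share at least 20% are marked where their value is printed, a limit set after the shares were seen. Those with 10% to 20% were THAP11 (18.0%), ROBO4 (16.9%), EIF2B1 (15.6%), RPL26 (14.3%), MRPL49 (12.2%), VIPR1 (11.4%), WDR5 (11.2%), GINS3 (10.9%), WARS1 (10.6%) and IFIT2 (10.3%).

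Counts were tested with edgeR 4.0.16 in R 4.3.3. Genes were filtered with filterByExpr, libraries were scaled by TMM, and shPML was compared with shC by the quasi-likelihood test with group as the term and Benjamini-Hochberg adjusted p under 0.05. Rises and falls are calls at that threshold. Levels are TMM-scaled CPM, given as mean ± SD over 3 libraries, and the SE of a log2 fold change is its size divided by the square root of the F statistic, an approximation. The biological coefficient of variation was 14.7%.

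The test, the gene lists, the rule for named genes and the alternatives were fixed before the data were examined, except the alternatives with a GC offset, which were chosen after the data were seen. The lists, 30 in all, came from textbook knowledge. They cover cytosolic ribosomal proteins (all, large subunit and small subunit), mitochondrial ribosomal proteins, ribosome biogenesis and RNA polymerase I, translation factors, mTOR pathway components, the RONIN and HCF-1 complex, other PML nuclear body components and cyclin-dependent kinase inhibitors. They also cover p53 targets, secreted factors of senescent cells, G1/S and DNA replication, G2/M and mitosis, replication-dependent histones, interferon-stimulated genes, hypoxia targets, nuclear genes of oxidative phosphorylation, mitochondrially encoded mRNAs and ATF4 targets. The others are endoplasmic reticulum chaperones, cholesterol synthesis and uptake, lysosome and autophagy, mesenchymal and matrix genes, YAP/TAZ targets, 4 lists of markers of luminal, stromal, haematopoietic and endothelial cells, and the 16 individually fixed genes. The marker lists share 0 genes with the other lists apart from the fixed genes.

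Lists with at least 5 measured members, 27 of the 30, were tested with camera (limma 3.58.1) at a preset correlation between genes of 0.01, adjusted over the lists. Camera with an estimated correlation rests on the 4 residual degrees of freedom of the 6 libraries, and no list passed with it, in the full data, without shC replicate 3 or with the GC offset. The fry test, which asks whether the members move on balance in 1 direction, stood beside it. The large and small ribosomal subunits were compared by 100000 permutations of genes.

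Named genes were the 16 fixed genes, the 10 largest rises and 10 largest falls among called genes with an average log2 CPM of at least 3 and no overlap between the groups, and examples of each list. The examples were up to 2 called members with the smallest p in the direction of the larger count and 1 in the other direction, or the highest expressed member where none was called. Genes named outside this rule are said to be chosen after their values were seen.

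The alternatives were DESeq2 1.42.0, limma-voom, RLE and upper-quartile scaling, no filter on low counts, a CPM of at least 1 in 3 libraries, each library left out in turn, the replicate number as a block, an offset for gene length with and without the block, limma on log2(FPKM + 1) and on log2(FPKM + 0.1), an offset for GC content with and without the block, and a test against a 1.5-fold change. The GC offset is a spline of 5 degrees of freedom per library on the GC content of the longest transcript, known for 97.7% of tested genes. Figures and tables were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

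The scripts were tested on simulated counts for the 13887 tested genes. Without a GC trend, edgeR recovered 28.4% of 67 genes changed 1.5-fold, 62.7% of 67 changed 2-fold and 89.4% of 66 changed 4-fold, with 10 false among 130 calls. With the GC trend of the real libraries it recovered 1.5%, 49.3% and 84.8%, with 1 false among 91 calls, and the GC offset then recovered 16.4%, 71.6% and 87.9%, with 11 false among 132. Without a GC trend, a list of 79 genes shifted by -0.35 on the log2 scale was found at a median of -0.35 (camera adjusted p = 2.68e-17, and 0.0284 with an estimated correlation), and 0 of 100 unshifted lists were called by camera. With the GC trend of the real libraries the shifted list was found at a median of -0.392, too low, and at -0.365 with the GC offset. The simulated genes were drawn independently of each other. In the real data the estimated correlation between genes was 0.192 for the cytosolic ribosomal protein list and 0.181 for the G2/M list. The simulation therefore cannot show how often camera at the preset correlation calls such correlated lists falsely.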

Results

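RNA was sequenced from MDA-MB-231, an established human triple-negative breast cancer cell line, carrying a short hairpin RNA against PML (shPML, 3 libraries) or a control construct (shC, 3 libraries). PML is the scaffold protein of PML nuclear bodies. The title of the series names PML, mTOR and RONIN (encoded by THAP11) together with ribosomal genes and senescence. The comparison of shPML with shC asks which transcripts differ when PML is lowered. Reads counted on genes totalled 20074657, 20455656 and 21609927 in shC replicates 1, 2 and 3. They totalled 19732542, 17729472 and 21418204 in shPML replicates 1, 2 and 3. Between 19398 and 20354 genes had a count in a library. The labels do not say that the replicates were separate cultures, so the p-values measure only the spread between these 6 libraries, which may be technical.

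The 2 groups separated on the first principal component of log2 CPM, which held 56.0% of the variance. The shPML libraries lay close together, with correlations of log2 CPM across genes from 0.9933 to 0.9939, while those among the shC libraries ranged from 0.9738 to 0.9915 (genes are not independent replicates). shC replicate 3 stood apart from the other shC libraries by the GC content of its transcripts. A smooth GC trend held 52.2% of the variance across genes of its log2 difference from them, against 25.6% for shC replicate 2 minus shC replicate 1 and 0.511% to 5.73% among the shPML libraries. In shC replicate 3, the 10% of genes with the lowest GC content lay at a median log2 difference of -0.71 from the other shC libraries. The 10% with the highest GC content lay at 0.52. shC replicate 1 leaned the other way. Against each gene's mean over the 6 libraries it lay at 0.239 in the lowest of 10 GC bins and at -0.242 in the highest. Leaving out shC replicate 3 therefore does not remove GC differences among the shC libraries. Between the group means a GC trend held 5.48% of the variance. Counts of calls are therefore also given without shC replicate 3 and with a per-library GC offset, both of which raised the number of changed genes.

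**Figure D1:**
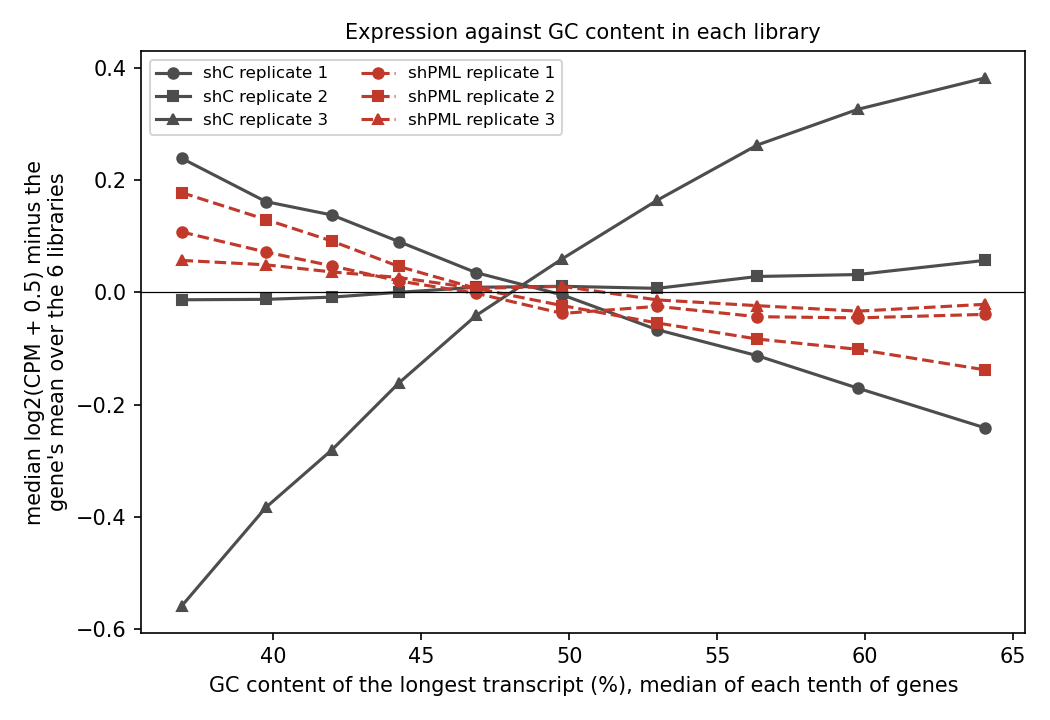
Median log2(CPM + 0.5) of genes in 10 bins of GC content (%), as the difference from each gene's mean over the 6 libraries, with 1 line per library (shC solid, shPML dashed). shC replicate 3 rises with GC content, shC replicate 1 falls with it from 0.239 to -0.242, and the 3 shPML libraries lie within 0.2 of 0 in every bin.

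PML (ENSG00000140464), the target of the hairpin, was lower in all 3 shPML libraries. Its counts were 1758, 1994 and 2540 in shC replicates 1, 2 and 3 and 1414, 1109 and 1361 in shPML replicates 1, 2 and 3. After TMM scaling the level fell from 103.4 ± 20.5 CPM (SD, n = 3) in shC to 64.8 ± 4.51 CPM (SD, n = 3) in shPML, a log2 fold change of -0.68 (SE 0.15, edgeR adjusted p = 0.0214). PML thus fell by 37.4%. The fall was smaller without shC replicate 3 (log2 fold change -0.50, edgeR adjusted p = 0.000878) and with the GC offset (-0.54, 0.000104). The call of the PML log2 fold change was lost without shC replicate 2 (-0.72, edgeR adjusted p = 0.0767) and without shPML replicate 1 (-0.73, 0.0766), 2 (-0.64, 0.107) or 3 (-0.66, 0.101). The adjusted p of PML ranged from 0.000104 to 0.107 over all its alternatives in edgeR, DESeq2 and limma.

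LMNB1, which encodes lamin B1 of the nuclear lamina and is lower in many senescent cells, fell from 246 ± 6.59 to 100.1 ± 3.35 CPM (SD, n = 3; log2 fold change -1.29, SE 0.09, edgeR adjusted p = 0.000297). CDKN1B, which encodes the cell cycle inhibitor p27, rose from 38.1 ± 2.02 to 64.2 ± 1.11 CPM (log2 fold change 0.75, SE 0.10, edgeR adjusted p = 0.00274). SOX9, a transcription factor of progenitor cells, fell from 134.9 ± 13.8 to 74.9 ± 3.23 CPM (log2 fold change -0.85, SE 0.11, edgeR adjusted p = 0.00274). MYC, a transcription factor that drives growth and ribosome production, fell from 300.5 ± 55.2 to 201.8 ± 7.41 CPM (log2 fold change -0.57, SE 0.14, edgeR adjusted p = 0.0271). The MYC call was lost without shC replicate 2 (edgeR adjusted p = 0.0964) and without shPML replicate 1 (0.125), 2 (0.121) or 3 (0.0978), within a range of 0.000191 to 0.125 over its alternatives. CDKN1A, which encodes the cell cycle inhibitor p21, had a log2 fold change of 0.39 (edgeR adjusted p = 0.0596) and passed without shC replicate 3 (0.44, 0.00604), with adjusted p from 0.00185 to 0.221 over its alternatives. The kinase gene PIM1 had -0.39 (edgeR adjusted p = 0.096), the hypoxia factor gene HIF1A 0.17 (0.571; 0.35 without shC replicate 1, -0.02 without shC replicate 3 and -0.01 with the GC offset) and the chemokine gene CXCL8 1.07 (0.0983). PIM1 lay at -0.23 without shC replicate 3 (edgeR adjusted p = 0.0666) and passed without shC replicate 1 (-0.48, 0.0288; range over its alternatives 0.00918 to 0.275), as did CXCL8 (1.56, 0.0128; range 0.0117 to 0.291). Of the 14 individually fixed genes that were measured, 1 rose and 4 fell, or 3 and 6 adjusted over the list alone, with a median of -0.14 (camera adjusted p = 0.481). The counts were 3 and 7 without shC replicate 1 and 4 and 5 without shC replicate 3, and 2 fell without any other library. With the GC offset 6 rose and 6 fell. CDKN2A and IL6 were below the count filter. Their summed counts were 1 in shC against 12 in shPML for CDKN2A (ratio of CPM 12.7, 95% interval 1.87 to 541.4) and 1 against 15 for IL6 (ratio 15.8, 2.44 to 666.4), intervals that cover counting error only. IL6 shares 20.7% of its exonic bases with other genes.

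**Figure D2:**
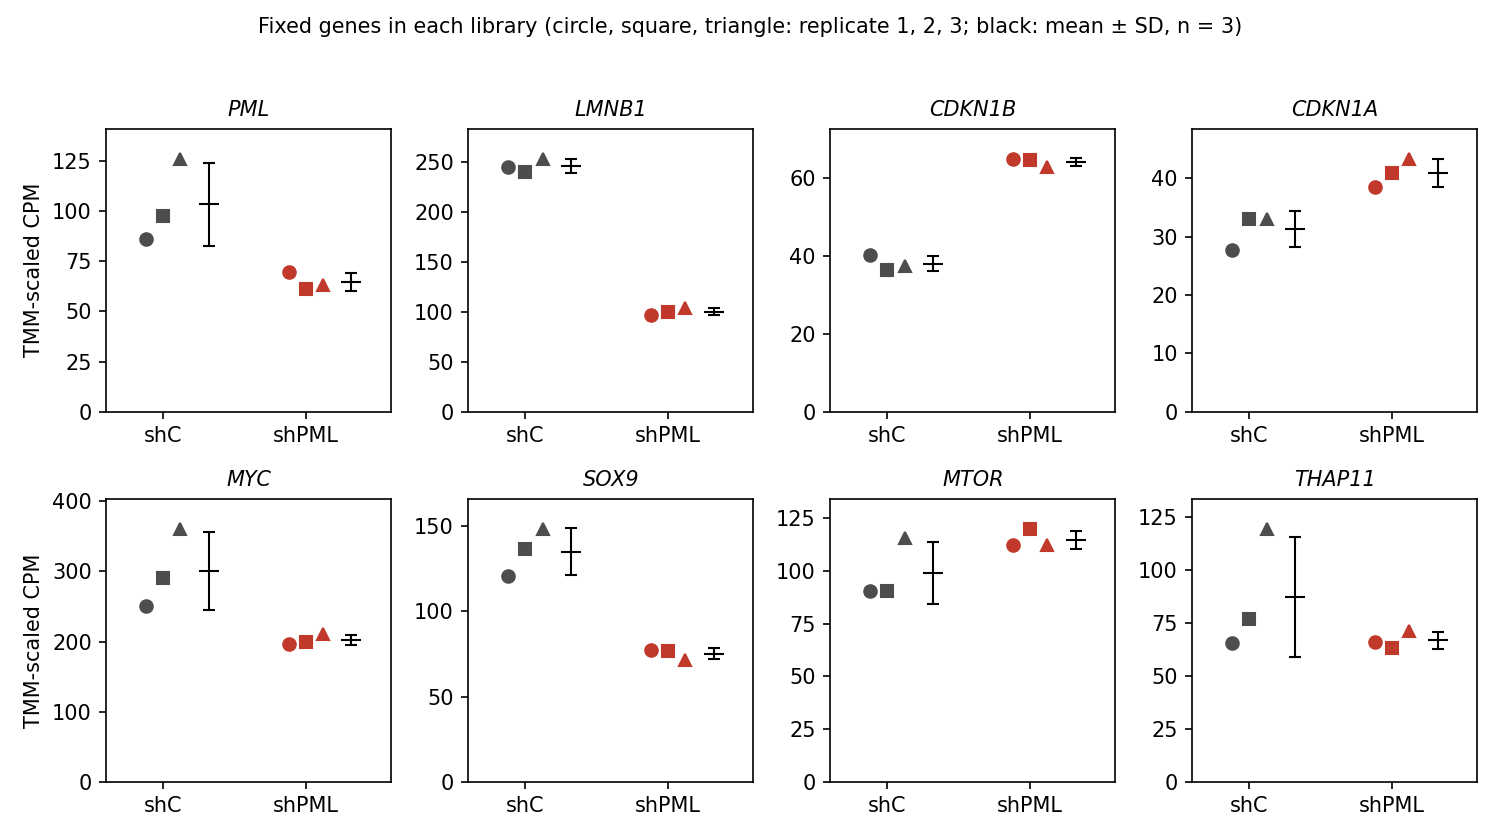
TMM-scaled CPM of 8 fixed genes in each library (grey shC, red shPML; circle, square and triangle for replicates 1, 2 and 3) with the mean ± SD of each group (n = 3). For PML, LMNB1, CDKN1B, CDKN1A, MYC and SOX9 the 3 shPML libraries do not overlap the 3 shC libraries, while for MTOR and THAP11 they do.

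Of 13887 genes tested, 2064 changed (14.9%). Of these, 953 were higher and 1111 lower in shPML. By at least 2-fold, 317 were higher and 281 lower. In all 2064 the groups did not overlap. Over all tested genes this held for 5426 (39.1%). For a single gene, 10% of the ways to divide 6 libraries into 3 and 3 would give this by chance. Genes that share a trend move together, so 10% is not a firm expectation for 1 given division. The largest rise among expressed genes was VIPR1 (ENSG00000114812), a receptor for vasoactive intestinal peptide, from 0.62 ± 0.07 to 15.5 ± 0.68 CPM (SD, n = 3; log2 fold change 4.63, SE 0.17, edgeR adjusted p = 3.9e-05). It was followed by the growth factor gene PDGFB (log2 fold change 3.10), the actin-severing protein gene SCIN (2.95), the water and glycerol channel gene AQP3 (2.86), MEGF6 (2.64), the immune checkpoint gene VSIR (2.58), the membrane-bound transcription factor gene CREB3L1 (2.38), MISP (2.30), VSTM2L (2.18) and RGL1 (2.07). By the rule for named genes, which asks for an average log2 CPM of at least 3, the largest fall was that of JMJD8 (ENSG00000161999), from 40.5 ± 9.06 to 8.39 ± 1.13 CPM (log2 fold change -2.27, SE 0.20, edgeR adjusted p = 0.000596). It shares 37.4% of its exonic bases with STUB1 on the opposite strand, so its value is uncertain. PRPS2, which makes the ribose donor of nucleotide synthesis, fell from 67.6 ± 3.07 to 15.6 ± 0.91 CPM (log2 fold change -2.12), and TGM2, a protein-crosslinking transglutaminase, from 338.5 ± 69.6 to 90.1 ± 2.86 CPM (-1.91). The other largest falls by the same rule were those of the protease gene BACE2 (log2 fold change -2.00), the lipolysis cofactor gene ABHD5 (-1.87), the BMP antagonist gene NOG (-1.83), the peptide hormone gene APLN (-1.82), the kinase gene HIPK3 (-1.80), the death receptor gene TNFRSF21 (-1.78) and SLC44A2 (-1.72). Without shC replicate 1 or 3 the number of changed genes was 3722 or 4402, and without shC replicate 2 or shPML replicate 1, 2 or 3 it was 701, 624, 649 or 627. Of the 2064 genes, 2053 were also called in the same direction without shC replicate 3 and 2042 with the GC offset, which called 5210.

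Transcripts of cytosolic ribosomal proteins, the protein components of the cytoplasmic ribosome, were lower in shPML as a group with the preset correlation. Of 79 measured genes, 37 fell and 42 did not pass the edgeR test, and 24 of the 79 lay above 0. Adjusted over the list alone, 39 fell and 3 rose. The median log2 fold change was -0.35 (camera adjusted p = 3.04e-06, but adjusted p = 0.633 with an estimated correlation). Fry, which compares with no other genes, passed for this list (adjusted p = 0.0228) and the large subunit (0.00926), but not the small subunit (0.0912). RPL26 fell from 18.5 ± 1.40 to 6.77 ± 0.31 CPM (SD, n = 3; log2 fold change -1.45, SE 0.13, edgeR adjusted p = 0.000609), and RPS14 from 909.7 ± 114.8 to 414.1 ± 25.4 CPM (-1.14, SE 0.11, 0.00106). Of 47 large-subunit genes, 27 fell (28 fell and 1 rose adjusted over the list alone), with a median of -0.47 (camera adjusted p = 2.69e-07, but adjusted p = 0.582 with an estimated correlation). Among them RPL7 fell from 907 ± 39.7 to 561 ± 17.7 CPM (log2 fold change -0.69). Of 32 small-subunit genes, 10 fell (11 fell and 2 rose adjusted over the list alone), among them RPS4X (log2 fold change -0.56), with a median of -0.11 (camera adjusted p = 0.113, and 0.642 with an estimated correlation). The difference of -0.36 between the medians of the subunits did not pass a two-sided permutation test over genes (p = 0.0934), which are not independent replicates. Adjusted over all tested genes, 0 of the 79 were called higher with all 6 libraries by edgeR without an offset or by DESeq2, where 4 and 3 were higher at an unadjusted p under 0.05. With the GC offset 7 rose and 40 fell, with the GC offset and the block 11 rose and 41 fell, with the length offset 1 rose, and in the limma fits to FPKM 3 rose.

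Fewer ribosomal protein genes were called when shC replicate 2 or a shPML library was left out. Those that fell numbered 21 without shC replicate 2 and 13, 15 and 23 without shPML replicate 1, 2 and 3. The corresponding numbers were 16, 11, 13 and 17 for the large subunit and 5, 2, 2 and 6 for the small subunit. Without shC replicate 3, 42 fell and 12 rose, and without shC replicate 1, 37 fell and 2 rose. For the small subunit the median was -0.03 without shC replicate 3, where 13 fell and 8 rose, -0.19 without shC replicate 1, -0.07 without shPML replicate 1 and -0.04 with the GC offset. The small-subunit list passed camera under DESeq2, without a low-count filter, without shC replicate 2 and without shPML replicate 3 (adjusted p = 0.0215, 0.0304, 0.0477 and 0.0389; range 0.0215 to 0.642 over its alternatives). Values of RPL10, RPS10, RPL17, RPS2, FAU, RPL30, RPS28 and RPS25, which share 55.5%, 39.4%, 35.3%, 25.6%, 22.6%, 21.6%, 21.4% and 20.8% of their exonic bases with other genes, and of members with pseudogene copies, are uncertain.

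**Figure D3:**
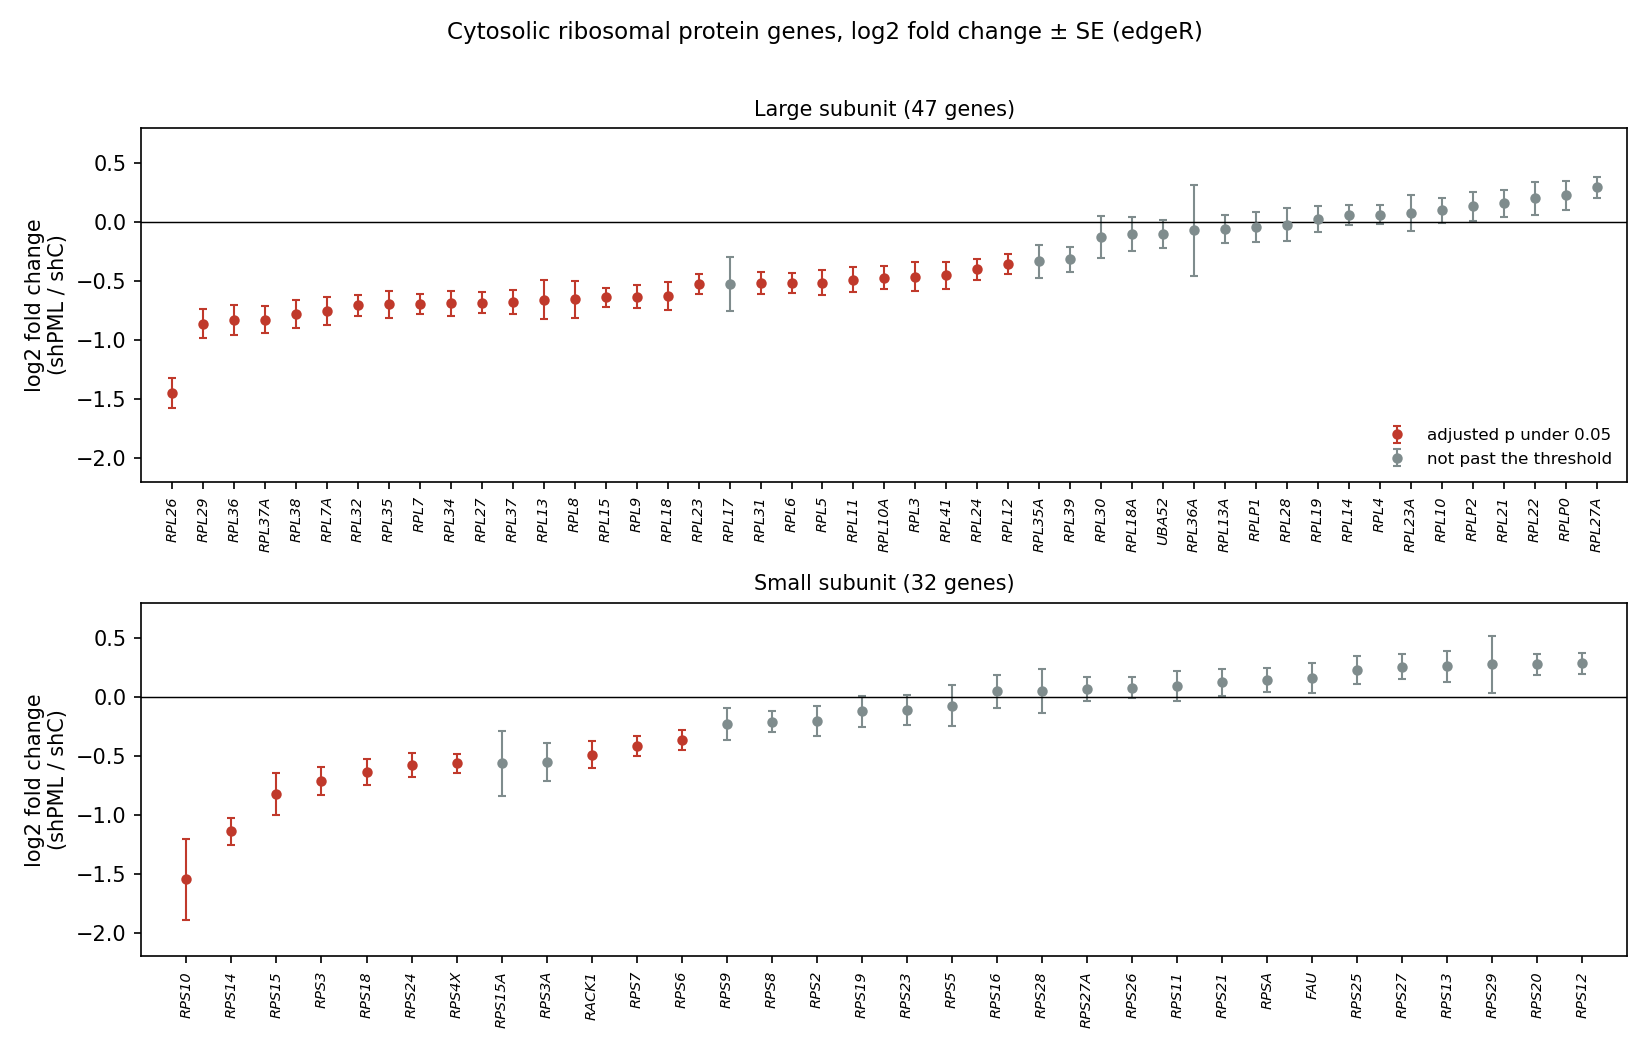
Log2 fold change (shPML over shC) ± SE of each measured ribosomal protein gene, sorted by value, for the large (47 genes) and the small subunit (32 genes). Red points passed edgeR's adjusted p threshold of 0.05: 27 in the large and 10 in the small subunit, all below 0.

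The other lists of the translation machinery did not pass camera in the fit fixed beforehand. Of 74 mitochondrial ribosomal protein genes, 4 fell (1 adjusted over the list alone) and 70 did not pass, with a median of 0.05 (camera adjusted p = 0.973). MRPL49 and MRPS23 fell by 0.53 and 0.39 on the log2 scale. Of 63 genes of ribosome biogenesis and RNA polymerase I, 1 fell (1 adjusted over the list alone) and 62 did not pass, with a median of -0.08 (camera adjusted p = 0.225). The member that fell was NOP2, a ribosomal RNA methyltransferase (log2 fold change -0.76), which shares 54.4% of its exonic bases with another gene, so its value is uncertain. Of 40 translation factor genes, 1 rose and 3 fell (1 and 2 adjusted over the list alone), among them the start-site factor EIF1 (log2 fold change 0.53), EIF2B1 of the guanine nucleotide exchange factor (-0.64) and the scaffold EIF4G1 (-0.58). Their median was 0.03, but their mean was -0.01 and camera's direction was down (camera adjusted p = 0.973). Leaving out 1 library moved the medians of the mitochondrial ribosomal protein genes and the translation factor genes to as low as 0.012 and 0.011 (both without shC replicate 3), and the latter to 0.054 without shC replicate 1. The ribosome biogenesis list passed without shC replicate 3 (camera adjusted p = 0.0247, range 0.0247 to 0.633 over its alternatives), where 12 fell and 1 rose, but not with an estimated correlation (adjusted p = 0.498). In the fit without shC replicate 1, 11 fell and 1 rose. Without shC replicate 1 or 3, 6 or 11 mitochondrial ribosomal protein genes rose and 8 or 7 fell. In the same fits 4 translation factor genes rose and 5 or 6 fell. Without any of the other 4 libraries, 1 translation factor gene and no mitochondrial ribosomal protein gene fell. With the GC offset, 13 mitochondrial ribosomal protein genes rose and 11 fell, 2 ribosome biogenesis genes rose and 16 fell, and 6 translation factor genes rose and 7 fell. The calls of MRPL49, MRPS23, EIF4G1 and EIF1 were lost without shC replicate 2 or shPML replicate 1, 2 or 3 (highest edgeR adjusted p 0.0766, 0.164, 0.0667 and 0.0692).

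Among 34 components of the mTOR pathway, a nutrient-sensing kinase pathway, 2 rose (1 adjusted over the list alone) and 32 did not pass, with a median of 0.07 (camera adjusted p = 0.426). The members that rose were SESN3 (from 11.6 ± 2.83 to 29.8 ± 3.39 CPM, SD, n = 3; log2 fold change 1.37) and SESN1 (0.64), which encode sestrins, inhibitors of mTOR signalling. MTOR itself had a log2 fold change of 0.21 (SE 0.12, edgeR adjusted p = 0.272), RPTOR 0.11 (0.706) and RICTOR 0.39 (0.27). Of 7 genes of the RONIN and HCF-1 complex, 1 rose and 1 fell (2 and 1 adjusted over the list alone), with a median of -0.075 (camera adjusted p = 0.481; fry, which compares with no other genes, 0.00359; range 0.00359 to 0.642 over alternatives). WDR5, a scaffold of histone methyltransferase complexes, fell from 159.4 ± 6.63 to 52.0 ± 2.18 CPM (log2 fold change -1.62, SE 0.09, edgeR adjusted p = 0.000182), and the glycosyltransferase gene OGT rose (0.61). THAP11 had a log2 fold change of -0.39 (edgeR adjusted p = 0.241) and HCFC1 of -0.44 (0.116). Of 30 other components of PML nuclear bodies, 2 fell (2 adjusted over the list alone) and 28 did not pass, with a median of 0.07 (camera adjusted p = 0.754). Those that fell were the kinase gene HIPK2 (log2 fold change -0.56) and the modifier gene SUMO3 (-0.47).

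Several of these values changed when 1 library was left out or a GC offset was added. Without shC replicate 3, THAP11 had a log2 fold change of -0.09 (edgeR adjusted p = 0.491), whereas without shC replicate 1 it was called lower (-0.56, 0.0386; range 0.0284 to 0.491 over its alternatives). HCFC1 was called lower without shC replicate 1 (-0.56, edgeR adjusted p = 0.0206) and 3 (-0.20, 0.0358; range 0.00434 to 0.282). MTOR and RPTOR were called higher without shC replicate 3 (0.35 and 0.35, edgeR adjusted p = 0.00321 and 0.00543; ranges 0.00321 to 0.592 and 0.00543 to 0.921), and RICTOR without shC replicate 1 (0.61, 0.0418; range 0.04 to 0.513). RPTOR lay at -0.04 without shC replicate 1 and 0.04 without shC replicate 2, and RICTOR at 0.17 without shC replicate 3 (edgeR adjusted p = 0.258). Without shC replicate 1 or 3, 5 or 9 mTOR pathway genes rose and 3 or 1 fell, 2 or 1 genes of PML nuclear bodies rose and 3 or 2 genes of the RONIN and HCF-1 complex fell. Without any of the other 4 libraries 1 mTOR pathway gene rose. Without shC replicate 1 the medians of the mTOR pathway, the RONIN and HCF-1 complex and PML nuclear bodies were 0, -0.006 and 0.14, and that of PML nuclear bodies was 0.008 without shC replicate 3. With the GC offset, 12 mTOR pathway genes rose and 3 fell, and MTOR, RPTOR and RICTOR were called higher (log2 fold change 0.30, 0.26 and 0.21, edgeR adjusted p = 0.00496, 0.00762 and 0.04). In the same fit 2 genes of the RONIN and HCF-1 complex rose and 2 fell (median -0.23), HCFC1 was called lower (-0.29, edgeR adjusted p = 0.00434), and 2 genes of PML nuclear bodies rose and 4 fell. The calls of SESN1, OGT, HIPK2 and SUMO3 were lost without shC replicate 2 or shPML replicate 1, 2 or 3 (highest edgeR adjusted p 0.142, 0.174, 0.0793 and 0.0998).

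Secreted factors of senescent cells moved in both directions. Of 29 measured, 4 rose and 6 fell (5 and 7 adjusted over the list alone), with a median of -0.03 (camera adjusted p = 0.584). ICAM1, a leukocyte adhesion receptor, rose from 1.0 ± 0.33 to 4.66 ± 0.50 CPM (SD, n = 3; log2 fold change 2.21, SE 0.25, edgeR adjusted p = 0.00162), while 23.6% of its exonic bases are shared with other genes. The growth factor binding protein gene IGFBP3 fell from 54.3 ± 5.10 to 25.01 ± 1.17 CPM (log2 fold change -1.12) and the glycoprotein hormone gene STC1 fell (-1.12). Also chosen after their values were seen, the collagenase gene MMP1 and the stromelysin gene MMP3 fell (log2 fold change -1.48 and -2.41), while EREG and CCL2 rose (1.36 and 1.13). Of 5 cyclin-dependent kinase inhibitors measured, 1 rose (CDKN1B) and 4 did not pass (2 rose and 1 fell adjusted over the list alone), with a median of 0.27 (camera adjusted p = 0.426). Of 25 p53 target genes, 2 rose and 2 fell (5 and 2 adjusted over the list alone), with a median of 0.15 (camera adjusted p = 0.426). PLK2 and SESN1 rose (log2 fold change 0.54 and 0.64), whereas PPM1D, a phosphatase that limits p53, fell (-0.54). Of 33 lysosome and autophagy genes, 6 rose and 1 fell (7 and 2 adjusted over the list alone), with a median of 0.10 (camera adjusted p = 0.15). The acid ceramidase gene ASAH1 and the acid lipase gene LIPA rose (log2 fold change 0.95 and 1.15) and the sialidase gene NEU1 fell (-0.90).

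Without shC replicate 3 the median of the secreted factors was 0.06, of opposite sign and with no call (7 rose and 7 fell). With the GC offset it was 0.08 (7 rose and 8 fell), again with no call. The lysosome list passed without shC replicate 3 (camera adjusted p = 0.0135, range 0.0135 to 0.642 over its alternatives), where 11 rose, and with the GC offset (median 0.16, camera adjusted p = 0.0182), but with an estimated correlation in neither (adjusted p = 0.498 and 0.341). Only 2 rose without shC replicate 2 or a shPML library. Of the p53 targets, 6 or 7 rose without shC replicate 1 or 3 and at most 1 without any other library, and of the cyclin-dependent kinase inhibitors 3 rose without shC replicate 3. The median of these inhibitors was 0.11 without shC replicate 1, 0.44 without shC replicate 3 and 0.42 with the GC offset, and that of the p53 targets was 0.09 without shPML replicate 2. Under the GC offset, 3 cyclin-dependent kinase inhibitors, 9 p53 targets and 14 lysosome genes rose, and 3 p53 targets and 4 lysosome genes fell. The call of PPM1D was lost without shC replicate 2 or shPML replicate 1, 2 or 3 (highest edgeR adjusted p 0.106), that of NEU1 without shPML replicate 1, 2 or 3 (0.0633), and that of PLK2 without shC replicate 2 or shPML replicate 2 or 3 (0.0597).

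Cell cycle transcripts were lower as groups with the preset correlation. Of 44 genes of G2/M and mitosis, 7 fell (7 adjusted over the list alone) and 37 did not pass, 40 lay below 0, and the median was -0.22 (camera adjusted p = 0.000771, but adjusted p = 0.633 with an estimated correlation). The mitotic kinesin genes KIF20A and KIF23 fell, from 229 ± 17.2 to 163 ± 6.74 and from 144 ± 21.9 to 96.5 ± 0.39 CPM (SD, n = 3; log2 fold change -0.49 and -0.58). Of 47 genes of G1/S and DNA replication, 1 rose and 7 fell (1 and 7 adjusted over the list alone), with a median of -0.18 (camera adjusted p = 0.0312, but adjusted p = 0.462 with an estimated correlation). The transcription factor gene E2F2 fell from 26.8 ± 3.73 to 14.9 ± 1.17 CPM (log2 fold change -0.85), GINS3 of the replicative helicase fell (-0.54), and MCM6 of the same helicase rose (0.55). Of 12 replication-dependent histone genes, 5 rose and 2 fell (5 and 2 adjusted over the list alone), with a median of 0.40 (camera adjusted p = 0.426). H1-2 and H2BC4 rose (log2 fold change 0.89 and 1.69) and H2BC12 fell (-0.61). The camera calls were lost without shC replicate 1 for both G2/M and G1/S (camera adjusted p = 0.0817 and 0.0906, ranges 6.97e-08 to 0.633 and 0.00538 to 0.462), and that of G1/S without shPML replicate 1 (0.0709). The G1/S call was also lost with the length offset (camera adjusted p = 0.0557) and in the limma fits to FPKM (0.0584 and 0.0609). The G2/M list did not pass fry (adjusted p = 0.155), whereas the G1/S list did (0.0228). The G1/S median was -0.10 without shC replicate 1 and -0.12 without shC replicate 2. Of the G2/M genes, 27 fell without shC replicate 3, 9 without shC replicate 1, and none (edgeR) without shC replicate 2 or shPML replicate 1, 2 or 3. In all 6 libraries 18 were lower at an unadjusted p under 0.05 (16 by DESeq2, which called 9). Of the G1/S genes, 13 and 18 fell without shC replicate 1 and 3, and at most 1 without any of the others. Of the histone genes, 3 rose without shC replicate 2 or a shPML library. Under the GC offset, 27 G2/M genes fell, 7 G1/S genes rose and 20 fell, and 5 histone genes rose and 2 fell. The calls of KIF20A, KIF23 and GINS3 were lost without shC replicate 2 or shPML replicate 1, 2 or 3 (highest edgeR adjusted p 0.0917, 0.098 and 0.0911), those of MCM6 and H2BC12 without shPML replicate 1, 2 or 3 (0.054 and 0.0631), and that of E2F2 without shPML replicate 1 or 3 (0.0537).

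Interferon-stimulated genes and targets of the integrated stress response were higher as groups with the preset correlation. Of 41 interferon-stimulated genes, 9 rose and 1 fell (12 and 1 adjusted over the list alone), with a median of 0.19 (camera adjusted p = 0.0312, but adjusted p = 0.462 with an estimated correlation). IFIT2 and IFIT1, antiviral proteins that bind foreign RNA, rose from 24.1 ± 4.54 to 51.4 ± 0.80 CPM and from 20.6 ± 4.55 to 41.2 ± 3.44 CPM (SD, n = 3; log2 fold change 1.10 and 1.0), and the peptide transporter gene TAP1 fell (-0.72). Of 29 targets of ATF4 in the integrated stress response, 10 rose and 19 did not pass (11 rose and 2 fell adjusted over the list alone), with a median of 0.11 (camera adjusted p = 0.0194, but adjusted p = 0.462 with an estimated correlation). CHAC1, which degrades glutathione, rose from 4.78 ± 0.34 to 10.1 ± 0.41 CPM (log2 fold change 1.08), and the tryptophanyl-tRNA synthetase gene WARS1 from 93.3 ± 4.13 to 141.4 ± 2.23 CPM (0.60). Of 19 endoplasmic reticulum chaperone and unfolded protein genes, 1 rose and 2 fell (2 and 4 adjusted over the list alone), with a median of -0.10 (camera adjusted p = 0.426). SEL1L rose (log2 fold change 0.52), and the chaperone genes CANX and PDIA4 fell (-0.55 and -0.35). Both camera calls were lost without shC replicate 1 (camera adjusted p = 0.0906 for the interferon-stimulated genes and 0.105 for the ATF4 targets; ranges 0.00359 to 0.462 and 0.00342 to 0.462 over alternatives). That of the interferon-stimulated genes was also lost without a low-count filter (camera adjusted p = 0.0759). The interferon-stimulated and ATF4 lists passed fry, which compares with no other genes (adjusted p = 0.00359 and 0.00567). Without shC replicate 3, 16 interferon-stimulated genes rose and 4 fell, and 15 ATF4 targets rose and 3 fell. The genes of the 2 lists that rose numbered 2 and 3 without shC replicate 2, 4 and 3 without shPML replicate 1, 3 and 3 without shPML replicate 2, and 2 and 3 without shPML replicate 3. Of the chaperone genes, 6 fell without shC replicate 3, 3 without shC replicate 1 and none without any other library. The median of the ATF4 targets was 0.22 without shC replicate 1, 0.31 without shC replicate 3 and 0.23 with the GC offset. With that offset 15 ATF4 targets rose and 4 fell, 18 interferon-stimulated genes rose and 6 fell, and 2 chaperone genes rose and 5 fell. The chaperone median was -0.003 without shC replicate 3. The calls of TAP1, CANX, PDIA4 and SEL1L were lost without shC replicate 2 or shPML replicate 1, 2 or 3 (highest edgeR adjusted p 0.0971, 0.0965, 0.184 and 0.166), and that of IFIT1 without shPML replicate 3 (0.0537).

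No metabolic list passed camera in the fit fixed beforehand. Of 24 genes of cholesterol synthesis and uptake, 1 rose and 3 fell (1 and 3 adjusted over the list alone), with a median of -0.05 (camera adjusted p = 0.397). DHCR7 of the last steps of the pathway and the mevalonate kinase gene MVK fell, from 247 ± 53.3 to 136.6 ± 9.21 and from 57.0 ± 13.7 to 31.5 ± 1.18 CPM (SD, n = 3; log2 fold change -0.86 and -0.85), and the sterol reductase gene TM7SF2 rose (1.55). Of 32 targets of hypoxia and HIF-1, 3 rose and 4 fell (3 and 4 adjusted over the list alone), with a median of -0.11 (camera adjusted p = 0.514). ANKRD37 fell (log2 fold change -1.99; uncertain, as 35.2% of its exonic bases are shared with UFSP2 on the opposite strand), the collagen-crosslinking enzyme gene LOX fell (-0.91) and TMEM45A rose (0.85). Of 73 nuclear genes of oxidative phosphorylation, 2 rose and 1 fell (1 and 1 adjusted over the list alone), with a median of 0.08 (camera adjusted p = 0.397). COX7C and ATP5F1A rose (log2 fold change 0.58 and 0.35) and ATP5MC1 fell (-0.58). Of the 13 mRNAs encoded in mitochondrial DNA, 0 changed in edgeR (0 adjusted over the list alone and 0 at an unadjusted p under 0.05) and 0 in DESeq2 (1 at an unadjusted p under 0.05), with a median of 0.08 (camera adjusted p = 0.426). MT-CO1 had 2995 ± 850 CPM in shC and 3941 ± 768 CPM in shPML (log2 fold change 0.40, and 0.19 without shC replicate 3 and 0.24 without shPML replicate 1). Mitochondrially encoded genes held 1.45%, 1.27% and 0.691% of the counts in shC replicates 1, 2 and 3 and 1.59%, 1.32% and 1.13% in shPML replicates 1, 2 and 3. Without shC replicate 3 the median of these mRNAs was -0.19, with 2 called lower, and without shC replicate 1 it was 0.45. With the replicate block 2 of them were called higher, with the block and the length offset 3, and with the block and the GC offset 4. Without shC replicate 1 or 3, 13 genes of oxidative phosphorylation rose and 4 fell, 7 or 6 genes of cholesterol synthesis fell and 5 or 6 hypoxia targets rose. Without any other library at most 1 gene of each of these lists rose. In the fit without shC replicate 3, 2 genes of cholesterol synthesis also rose and 6 hypoxia targets also fell. Under the GC offset, 18 genes of oxidative phosphorylation rose and 4 fell, 2 genes of cholesterol synthesis rose and 9 fell, and 5 hypoxia targets rose and 6 fell. The median of oxidative phosphorylation was 0.12 without shC replicate 1 and 0.04 without shC replicate 2. The hypoxia median was -0.02 without shC replicate 3 and -0.04 with the GC offset, and the cholesterol median was -0.11 and -0.12 without shC replicate 1 and 3. Over all its alternatives the cholesterol median lay between -0.119 and 0.03, a change of sign, with no call. The calls of MVK, ATP5F1A and ATP5MC1 were lost without shC replicate 2 or shPML replicate 1, 2 or 3 (highest edgeR adjusted p 0.0836, 0.144 and 0.0986), that of DHCR7 without shPML replicate 1, 2 or 3 (0.0631), and that of TMEM45A without shC replicate 2 or shPML replicate 1 or 3 (0.0597).

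Matrix, YAP/TAZ and luminal lists held calls but did not pass camera in the fit fixed beforehand. Of 26 mesenchymal and matrix genes, 7 rose and 6 fell (8 and 6 adjusted over the list alone), with a median of 0.14 (camera adjusted p = 0.426). The matrix proteins SPARC and THBS1 rose, from 30.4 ± 2.26 to 61.9 ± 0.28 and from 490.6 ± 66.5 to 1047 ± 17.4 CPM (SD, n = 3; log2 fold change 1.02 and 1.09), whereas fibronectin, FN1, fell from 106.7 ± 10.6 to 57.3 ± 0.39 CPM (-0.90). Of 19 targets of YAP/TAZ, the transcriptional coactivators of the Hippo pathway, 6 rose and 13 did not pass (7 rose and 2 fell adjusted over the list alone). Those that rose included the membrane repair gene MYOF (log2 fold change 0.81) and AJUBA (0.66). Their median was -0.07, but their mean was 0.17 and camera's direction was up (camera adjusted p = 0.381, range 0.0409, under DESeq2, to 0.642 over its alternatives). The median changed sign, with no call, to 0.05 both without shC replicate 3 and with the GC offset. Of 10 luminal epithelial markers measured, 2 rose and 8 did not pass (4 rose adjusted over the list alone), with a median of 0.50 (camera adjusted p = 0.0883). AGR2 and the adhesion molecule gene EPCAM rose, from 3.36 ± 0.72 to 8.57 ± 0.63 and from 2.48 ± 0.61 to 4.78 ± 0.81 CPM (log2 fold change 1.35 and 0.95). The summed luminal markers lay at 223, 250.4 and 339 CPM in shC replicates 1, 2 and 3 and at 381, 354 and 392.4 CPM in shPML replicates 1, 2 and 3, most of it KRT19. The luminal list passed without shC replicate 3 (median 0.75, camera adjusted p = 0.0165, range 0.0165 to 0.633 over its alternatives), where 5 rose, and with the GC offset (median 0.65, 0.0182), but with an estimated correlation in neither (adjusted p = 0.494 and 0.341). It also passed under DESeq2, without a low-count filter, without shPML replicate 2, and with the block and an offset for length or GC content (0.046, 0.0304, 0.047, 0.0447 and 0.0264). Of its members 3 rose without shC replicate 1 and 1 without any other library. Under the GC offset 6 luminal markers rose, 10 matrix genes rose and 7 fell, and 8 YAP/TAZ targets rose and 3 fell.

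Markers of other cell types were too few for a list test, and their counts adjusted over the list alone equalled those over all genes. Of 3 fibroblast and stromal markers measured, 1 rose (PDGFRB, log2 fold change 1.57) and 1 fell (COL1A1, -0.79), with a median of -0.52 but a mean of 0.09. Of 4 endothelial markers, 2 fell (ROBO4 and TIE1, log2 fold change -1.12 and -1.50). Of 2 haematopoietic markers, 0 changed in edgeR or DESeq2 (0 at an unadjusted p under 0.05). LAPTM5 had 104.0 ± 10.01 CPM in shC and 94.99 ± 1.13 CPM in shPML (SD, n = 3). Of the genes of the matrix list, 4 rose and 3 fell without shC replicate 2, and 3 rose and 3 fell without shPML replicate 1, 2 or 3. Of the YAP/TAZ targets, 3 rose without shC replicate 2 or shPML replicate 2 or 3. EPCAM and TIE1 were not called without shC replicate 2 or shPML replicate 1, 2 or 3 (highest edgeR adjusted p 0.127 and 0.128), nor COL1A1 without shPML replicate 2 or 3 (0.0725).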

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

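The results with a GC offset were chosen only after the GC trend in shC replicate 3 was seen; the other alternatives were planned. The number of changed genes (2064, 953 higher and 1111 lower) ranged from 624 to 4402 when 1 library was left out (284 to 2249 higher, 326 to 2153 lower): 3722 without shC replicate 1, 701 without shC replicate 2, 4402 without shC replicate 3, and 624, 649 and 627 without shPML replicates 1, 2 and 3. It was 5210 with the GC offset (2657 higher, 2553 lower), 5235 with the GC offset and the block (2688 and 2547), and 271 in the test against a 1.5-fold change (137 and 134), which asks for more by construction. Under DESeq2, the other scalings, filters, length offsets and FPKM fits it stayed within 1.5 times. No called gene changed direction under any alternative. The PML log2 fold change ranged from -0.79 to -0.50 with 1 library left out; its call was lost without shC replicate 2 (-0.72) and shPML replicate 1 (-0.73), 2 (-0.64) or 3 (-0.66). The ribosomal protein median, -0.35, lost its call with an estimated correlation (camera adjusted p = 0.633), and lay between -0.38 and -0.30 in all alternatives. The median of the secreted factors of senescent cells lay between -0.16 and 0.08 with no call. Over the alternatives of the other named genes, 1641 results were on the same side of the threshold, 130 lost and 34 gained a call; over those of the other lists, 472, 15 and 17. The cause of lost calls was not tested. At 17729472 to 21609927 counts per library, CDKN2A and IL6 lay below the count filter. Whether depth was the reason was not tested.

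The labels do not state that the replicate numbers pair the samples. The deviations of same-numbered libraries from their group means correlated at -0.04, 0.01 and 0.22 across genes. shPML replicates 1, 2 and 3 correlated best with shC replicates 2, 1 and 3. Deviations from a shared group mean are not independent of each other, and those of the shC libraries hold a GC trend. This check therefore cannot exclude a pairing. With the replicate block 1986 genes changed (957 higher, 1029 lower), 1741 of them among the 2064.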

Other observations

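The grouping of genes by symbol prefix, the genes named from it, and the tests of the GC trend and of swapped labels in shC replicate 3, were chosen only after the data were seen. Of 173 groups of measured genes with a shared prefix or of ribosomal protein pseudogenes, the RPL genes with their pseudogenes passed camera: 35 of 97 fell and 1 rose, with a median log2 fold change of -0.45 (camera adjusted p = 4.47e-07, but adjusted p = 0.993 with an estimated correlation). This group shares RPL genes with the large-subunit list tested above, where 27 of 47 fell, so its call is not independent of that one. Among the SOX transcription factor genes and their antisense genes, 1 of 10 rose and 5 fell, with a median of -0.54 (camera adjusted p = 0.121). SOX21 fell from 3.34 ± 1.13 to 0.74 ± 0.09 CPM (SD, n = 3; log2 fold change -2.17, edgeR adjusted p = 0.00428), whereas SOX6 rose from 0.94 ± 0.13 to 2.86 ± 0.19 CPM (1.61, 0.00329). Among 16 keratin (KRT) genes, antisense genes and pseudogenes included, 4 rose and 1 fell, with a median of 0.37 (0.56 without shC replicate 3, 0.51 with the GC offset; camera adjusted p = 0.34): KRT80 and KRT7 rose (log2 fold change 1.34 and 0.997) and KRT15 fell (-1.47). Of 21 collagen (COL) genes, 7 rose and 3 fell, with a median of 0.26 (0.44 without shC replicate 3, 0.36 with the GC offset; camera adjusted p = 0.34). Of 11 EXOC genes of the exocyst, which tethers secretory vesicles, 3 rose, with a median of 0.26 (camera adjusted p = 0.34); EXOC6B and EXOC4 rose (log2 fold change 1.002 and 0.60). Of 17 IFT genes of transport in cilia, 2 rose (IFT52 and IFT57, log2 fold change 0.74 and 0.41), with a median of 0.25 (camera adjusted p = 0.258).

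The distance of shC replicate 3 from the other shC libraries is consistent with a GC bias in that library. A GC trend held 52.2% of the variance of its difference from them. It also held 25.6% of that of shC replicate 2 minus shC replicate 1, so a GC trend was not confined to shC replicate 3. A label swapped with a shPML library is argued against by PML, which in shC replicate 3 lay 0.85 (log2) above the highest shPML library, while the shPML libraries spanned 0.19. Cells of another type stay open: the luminal markers were highest, at 1.355 times the higher of the other shC libraries, but in each of the 4 marker lists 1 gene that these cells express held over 50% of the sum, which would hide a small share. Where the GC trend arose was not tested.

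The lower median of cytosolic ribosomal protein transcripts in shPML may reflect the loss of PML, which is a hypothesis. A GC trend as the whole cause is argued against by the median after the GC offset, -0.348 (camera adjusted p = 0.000121), a length trend by that after the length offset, -0.327 (2.06e-05), and shC replicate 3 alone by that without it, -0.358 (0.000251; range 8.21e-10 to 0.633 over all alternatives). Fry, which compares with no other genes, passed with all 6 libraries (adjusted p = 0.0228). With an estimated correlation camera did not pass in the full data, with the GC offset or without shC replicate 3. A shared movement of these genes between libraries therefore stays open. Reads shared with pseudogenes also stay open: of 67 measured ribosomal protein pseudogenes, 1 rose and 6 fell, with a median of -0.24 (camera adjusted p = 0.0657). An effect of the hairpin on other targets is confounded with the group.

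The lower median of G2/M transcripts may likewise follow the hairpin, as a hypothesis. The median was -0.232 after the GC offset (camera adjusted p = 1.97e-07) and -0.273 without shC replicate 3 (6.97e-08; range 6.97e-08 to 0.633 over all alternatives), which argues against either as the whole cause. With an estimated correlation neither passed (adjusted p = 0.341 and 0.494), and without shC replicate 1 the call was lost (median -0.164, camera adjusted p = 0.0817), so that a shared movement of these genes between libraries stays open. A difference in growth or density between the cultures, and other targets of the hairpin, are confounded with the group and were not tested.

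Of the 10 splits of the 6 libraries into 3 and 3, 1, the real one, gave 2064 changed genes, and the highest of the others gave 0 in edgeR (at most 575 at an unadjusted p under 0.05). Each of the other splits put shC and shPML libraries on both sides, so the group difference entered the spread within sides. Their lack of calls therefore cannot decide on chance. The splits are too few for a share under 0.05.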
